A study of Arabidopsis thaliana with 8 samples.

How the data were processed

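Gene expression was measured on 8 single-colour Affymetrix arrays of Arabidopsis thaliana, each hybridised with material from total RNA of dark-grown seedlings of the wild-type accession Col-0. Per the labels, 4 arrays came from seedlings kept 72 h in the dark in air and 4 from seedlings kept 68 h in air and then exposed for 4 h to ethylene at 10 ppm, all 3 days old when frozen. The labels name 2 experiments and 2 replicas of each group in each experiment, so the arrays are called air 1-1, air 1-2, air 2-1, air 2-2 and likewise for ethylene, with the experiment first and the replica second. No label says that the replicas of an experiment were separate cultures. The p-values therefore measure only the spread between these samples, part of which may be technical.

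The values used were the authors' deposited table of processed intensity values, with 1 linear intensity per array for each of 22810 probe sets. In the deposited table the mean intensity left after removing the highest and lowest 2% of values was 2500.2 on every array, which points to a scaling of each array to a common target. Whether this was done by a single factor is not stated. The scanner software, the way probes were summarised into a probe set, and the detection calls are not given in the sources used here. A bright value on these arrays can saturate and a dim one can hold mostly background, and without detection calls neither could be marked. The median intensity per array lay between 833 and 980, and the medians of the log2 values lay between 9.73 and 9.96. This range was within the 0.3 log2 units allowed beforehand, and the deposited scaling was kept. The number of arrays limits the precision, and no depth of reads exists for such data.

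Intensities were converted to log2(intensity + 16). All differences between groups and folds are on this scale, which understates the change of dim probe sets. The 64 array control probe sets and the 30% of probe sets with the lowest mean over the 8 arrays were left out, and 15922 probe sets were tested. Ethylene was compared with air with limma 3.58.1 (lmFit, and eBayes with an intensity trend) in R 4.3.3, with group as the only term, and p-values were adjusted by the Benjamini-Hochberg method over all probe sets tested. A probe set was called at an adjusted p under 0.05. A second limma model had a mean for each experiment and group, and gave the ethylene effect within each experiment and the difference between experiments. Tables were prepared with Python 3.11.15 and pandas 2.3.3, and plots with matplotlib 3.10.9. Applied to data simulated for the comparison of ethylene with air over 15922 probe sets, with 200 changed in each of 5 simulations, the model without a block recovered 38.0% of changes of log2 1 and 86.2% of changes of log2 2. With the experiment as a block these shares were 68.4% and 96.0%. Of the calls in the simulated data, 1.01% were false without the block and 4.95% with it. The simulation gave both groups the same shift between experiments, and independent normal noise with the spread of the blocked model. Such data suit the blocked model, and replicas that resemble each other beyond this shift were not simulated. How far these shares carry over to the real arrays is therefore unknown.

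The labels state that the first number of a sample marks an experiment shared by both groups, so this first number links samples. As a check, the deviations of each array from its group mean were correlated across probe sets. The same-numbered pairs gave r = 0.327, 0.394, 0.593 and 0.464, all pairs from the same experiment gave at least 0.28, and all pairs from different experiments gave −0.25 or lower. The model with the experiment as a block was an alternative, and its values are given beside a result where it changed a call or moved a count by more than 1.5 times.

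Gene names came from the array's annotation table, in which 13513 probe sets name 1 gene, 503 name several and 8730 are not listed. Probe sets of the last 2 kinds were tested but left unnamed. Of the 13513, 13436 matched the RefSeq gene table of assembly TAIR10.1 by gene number, and 13350 different genes were named. A gene with several probe sets was represented by the one with the highest mean. No genome build is given for the array table, so no coordinates are reported. Of the 386 members of 23 gene lists, 56 had a named probe set and 51 were tested. Many well-known genes of these lists, such as ETR1, EIN2, ERF1, HLS1, ACT2 and UBQ10, had no named probe set in the annotation used here and are not analysed here.

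The gene lists, the tests, the filter, the pseudocount, most alternatives and the rule for named genes were set before the data were examined. The rule took the 8 genes with the largest increases and the 8 with the largest decreases among probe sets that name 1 gene, pass the threshold and differ in one direction in both experiments. It added all passing members of the ethylene perception and signalling list, up to 3 passing members of every other list (or the member with the smallest p where none passed) and the named genes ERF1, EIN3, EIN2, HLS1, ACT2 and UBQ10 where measured. Genes named outside this rule were chosen after their values were seen. Among list members these are RTH, ETP2, EXPA4, XTH18, EXPA18, LBD29, IAA18, YUC2, CHLM, GID1B and GID1C, and for genes of the added families the text says so. Lists with at least 3 tested members were tested as sets with camera at its preset correlation of 0.01, with camera at an estimated correlation, and with fry, and p-values were adjusted over the 8 lists so tested. A further 36 families, 29 of them with at least 5 tested members, were formed from gene symbols after the annotation had been seen, and another 2 families of enzymes were listed from memory after the largest changes had been seen. The means of those 2 families were tested by exact permutation of the group labels over all arrays and, added later, within experiments.

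Alternatives covered the experiment, the 4 pairs or the averaged replicas as a block, replicas as a random block, quantile and median scaling, pseudocounts of 1 and 64, no filter and a filter of 50%, eBayes without a trend, each experiment alone and each array left out in turn. Each array left out in turn was left out of the model without a block. This leaves unequal numbers of arrays per experiment in that array's group. The difference between experiments then enters both the comparison and its spread. A larger pseudocount and a blocked model without ethylene 2-2 were added after seeing the data.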

Results

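The series measured how gene expression in etiolated seedlings differs after a short exposure to the gaseous hormone ethylene. Etiolated seedlings are grown without light, and ethylene is known to shorten and thicken their hypocotyl and root and to tighten the apical hook. Each of the 2 groups, air and ethylene, had 4 arrays from 2 experiments, and each array gave 1 scaled intensity for each of 22810 probe sets. Treated seedlings had received 10 ppm ethylene for the last 4 h of their growth in the dark. The labels name seedlings and no organ, so a difference can come from any part of the seedling.

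The named gene with the largest increase was AT5G40590, whose intensity was 231 ± 37.8 in air and 7974 ± 1713 in ethylene (mean ± SD, n = 4), a 32.0-fold increase (SE 0.21 on the log2 scale, limma adjusted p = 2.02e-06). Genes for 2 class III peroxidases, secreted enzymes that act on cell wall components, also rose. AT5G19890 went from 1432 ± 595 to 27356 ± 10336, a log2 difference of 4.26, and AT1G49570 rose by 3.24. CYP718, a cytochrome P450, rose by 3.85 on the log2 scale, from 391 ± 239 to 5062 ± 610. AT2G39980, which encodes an acyltransferase of the BAHD family, reached an intensity of 50644 ± 16904 in ethylene against 5937 ± 2694 in air, a log2 difference of 3.14. The 8 largest increases also held XTH26, a xyloglucan endotransglucosylase, AT1G50110, a branched-chain aminotransferase, which rose 8.23-fold, and GH9B12, a glycosyl hydrolase of the endoglucanase family, which rose 6.83-fold. The adjusted p of these 8 genes ranged from 2.02e-06 for AT5G40590 to 0.0169 for XTH26. XTH26 was dim in air (105 ± 86.3), with 14.7 on 1 array, so the size of its increase is poorly fixed. Its log2 difference lay between 1.60 and 3.52 over the alternatives, and with a pseudocount of 1, or with 50% of probe sets left out, it was under the filter and not tested. Its call ended without ethylene 2-1 (adjusted p = 0.0524) or without ethylene 2-2 (0.0585). Blocking by experiment over all arrays gave it an adjusted p of 4.17e-05, and it also passed in the blocked model without ethylene 2-2. The differences of AT5G40590 and CYP718 ranged from 4.06 to 5.22 and from 2.99 to 4.72 over the alternatives, which include each experiment alone. AT5G40590 was less bright on ethylene 1-1 than on the other ethylene arrays.

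**Figure D1:**
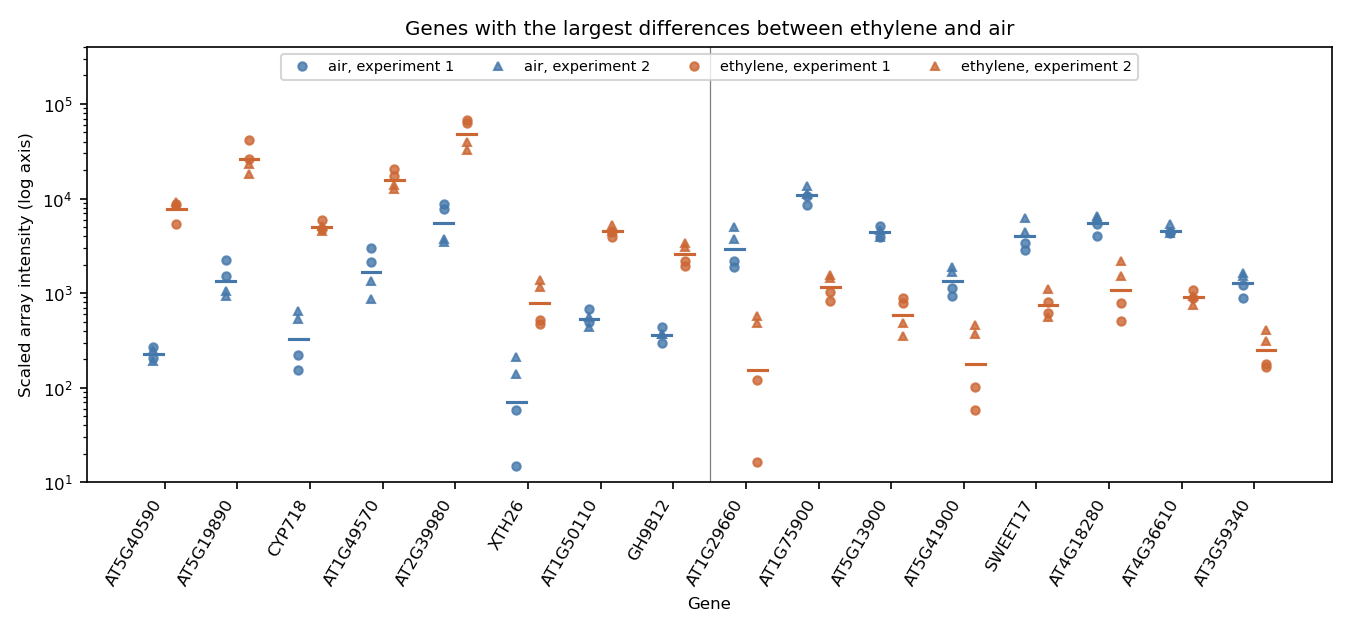
Scaled array intensity (log axis) of the 8 named genes with the largest increases, left of the line, and the 8 with the largest decreases, right of it, on the 4 air and 4 ethylene arrays. Points are single arrays, circles experiment 1 and triangles experiment 2, and bars are means of the log values; for each of these genes the 4 ethylene arrays lie on one side of all 4 air arrays, as for AT5G40590 with means of 231 and 7974.

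Among the genes that fell, AT1G29660 and AT1G75900, both of the GDSL esterase/lipase family, had the largest decreases. AT1G75900 fell by 3.19 on the log2 scale (SE 0.22, limma adjusted p = 4.7e-05), from 10979 ± 2080 in air to 1212 ± 346 in ethylene. AT1G29660 fell by 3.97 with a larger error (SE 0.79, limma adjusted p = 0.0173), and its intensity was 16.5 on 1 ethylene array. AT5G13900, a lipid-transfer protein gene, fell by 2.87, and the alpha/beta-hydrolase genes AT5G41900 and AT4G36610 had log2 differences of −2.77 and −2.32. SWEET17, a vacuolar fructose transporter, had an intensity of 4228 ± 1479 in air and 772 ± 241 in ethylene, a log2 difference of −2.41. AT4G18280 and AT3G59340 had differences of −2.33 and −2.29. The adjusted p of these 8 genes lay between 4.7e-05 and 0.0177. The sizes of some decreases moved with the pseudocount and between experiments, with differences of −4.94 to −2.69 for AT1G29660, −3.48 to −1.77 for AT5G41900 and −2.52 to −1.59 for AT3G59340 over the alternatives. AT1G29660 missed the threshold without air 2-1 (0.0542), air 2-2 (0.0513) or ethylene 1-2 (0.0606), and AT5G41900 without air 2-1 (0.0555) or air 2-2 (0.0571). Over all arrays with the experiment as a block their adjusted p was 1.98e-05 and 2.49e-05. AT4G36610 was brighter on air 2-1 than on the other air arrays.

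Several probe sets without a gene name in the annotation changed as strongly. The 2 largest increases among them were 4.57 and 4.52 on the log2 scale, and the 2 largest decreases −2.73 and −2.58. They were picked after their values were seen.

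In all, 249 probe sets were higher and 406 lower in ethylene at a limma adjusted p under 0.05, of 15922 tested. Of these, 173 were at least 2-fold higher and 228 at least 2-fold lower, and 119 of the higher and 212 of the lower named 1 gene. In each of the 655 called probe sets the 4 ethylene values lay on one side of the 4 air values. This held for 10.5% of all probe sets tested, and would for 2.86% if the 8 arrays were interchangeable. The arrays differ by experiment and the probe sets are not independent, so the excess over 2.86% is no test. The separation of called probe sets follows largely from how they were called. The median log2 difference over all tested probe sets was 0.01. With the experiment as a block the counts were 689 higher and 1170 lower, and all 655 probe sets called without it were among them. Of those called with the block, 340 of the higher and 581 of the lower named 1 gene. With the replicas of an experiment as a random block the counts were 119 and 130. The correlation of replicas estimated there was 0.458, while the main model treats them as independent. Leaving out 1 array could also move the counts. The number of lower probe sets was 243 without air 1-2, 214 without air 2-1, 238 without air 2-2, 246 without ethylene 1-2 and 266 without ethylene 2-2, and the number of higher ones was 164 without ethylene 1-2.

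Of the ethylene perception and signalling list, 4 of 20 members were measured by a named probe set, and 1 of them rose. This was RTE1, which encodes a regulator of the ethylene receptor ETR1 and went from 3036 ± 401 in air to 12680 ± 2742 in ethylene, a log2 difference of 2.04 (SE 0.18, limma adjusted p = 0.00017). EIN3, a transcription factor of the pathway that is known to be controlled largely through protein stability, differed by 0.16 (SE 0.19, adjusted p = 0.826), with intensities of 13696 ± 2383 and 15471 ± 3576. The differences of RTH, a relative of RTE1, and of ETP2, an F-box protein, were −0.24 and 0.04 and did not pass. As a set the list did not pass with camera (adjusted p = 0.256), while fry, which asks whether its genes moved on balance one way, gave 0.0173. The mixed form of fry, which asks whether genes moved in either direction, gave an adjusted p of 0.0071. The count was also 1 when adjusted over the list alone. From the ethylene biosynthesis list only ACO3 (AT1G12010), an ACC oxidase gene, was measured. Its difference of −0.96 did not pass (SE 0.31, adjusted p = 0.136), but passed with the experiment as a block (0.0258) and without ethylene 1-1 (0.0135). As the only tested member, adjustment over the list alone leaves its limma p as it was (0.00977).

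Among the genes of cell wall loosening on the list fixed beforehand, those that passed were lower in ethylene. Expansins are proteins that loosen the wall, and xyloglucan endotransglucosylases cut and rejoin its xyloglucan. Of 9 tested members of the list of these genes, none rose and 3 fell, and 4 fell when adjusted over the list alone or with the experiment as a block. With both, 4 fell and XTH18 rose (adjusted p = 0.0415). EXPA8 went from 24072 ± 5292 to 9145 ± 949, a log2 difference of −1.37 (SE 0.18, limma adjusted p = 0.00156). EXPA15 fell by 1.36 (SE 0.21, adjusted p = 0.00464) and the difference of XTH21 was −1.83 (SE 0.43, adjusted p = 0.0399), also a fall. The other 6 ranged from −0.71 for EXPA4, the member added by the block (adjusted p = 0.000825), to 0.46 for XTH18. The difference of XTH21 lay between −2.26 and −1.03 over the alternatives. With fry the list was lower as a set (adjusted p = 0.00637), and the mixed form gave 0.000349. It was lower with camera (adjusted p = 0.0196), but not without air 1-2 (0.0533) or ethylene 1-1 (0.0501). With an estimated correlation it did not pass (camera adjusted p = 0.174). The estimated correlation was −0.0156, below the preset, so a closer likeness of the members is not what raised this p. The XTH21 call ended without any 1 array other than ethylene 1-1 and ethylene 1-2 (adjusted p of 0.0521 to 0.121). Its adjusted p over all arrays with the block was 0.00784.

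All 3 tested members of the root hair list had positive differences, and 2 of them rose. Their products belong to the same classes of wall proteins as the preceding list. XTH26, whose increase is described above, and EXPA7, with a difference of 0.82 (SE 0.20, adjusted p = 0.0483), passed. EXPA18 differed by 0.44 (SE 0.18, adjusted p = 0.266) and passed when adjusted over the list alone and with the experiment as a block (0.0452). The list was higher as a set with camera (adjusted p = 0.0018), but not with an estimated correlation (adjusted p = 0.174). Fry gave an adjusted p of 0.0173, and its mixed form 0.234. EXPA7 lay close to the threshold, and its call ended with median scaling (0.0512) and without any 1 array other than air 2-1 (0.0687 to 0.135). Its adjusted p over all arrays with the block was 0.00622.

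Of 7 tested auxin-responsive genes, 1 rose and 1 fell, and with adjustment over the list alone, or with the experiment as a block, 1 rose and 2 fell. The second fall with the block was that of LBD29, named after its values were seen, with a difference of −1.68 (SE 0.47, adjusted p = 0.0855, or 0.0105 with the block). With the block and adjustment over the list alone IAA18, at 0.30, rose as well (adjusted p = 0.0471), also named after its values were seen. IAA20, which encodes an Aux/IAA repressor of auxin responses, rose by 1.09 (SE 0.22, adjusted p = 0.0214). GH3.3, whose product conjugates auxin to amino acids, fell by 0.80 (SE 0.19, adjusted p = 0.0457). The mean of the list was −0.14 and its median 0.12, and camera, which gave an upward direction, did not pass (adjusted p = 0.841). Fry gave an adjusted p of 0.919, while its mixed form gave 6.61e-05, with members moving both ways. The IAA20 call ended without air 2-1, air 2-2, ethylene 1-2, ethylene 2-1 or ethylene 2-2 (0.0516 to 0.0655), and the GH3.3 call without any 1 array other than air 2-2 and ethylene 2-1 (0.0751 to 0.129). Over all arrays with the block their adjusted p was 0.00187 and 0.0055. From the auxin synthesis and transport list, the 2 tested genes were YUC2 and YUC6, and neither passed. YUC6 had a difference of −0.05 (SE 0.27, adjusted p = 0.976). The cytokinin response list had 1 tested member, RR16 (also ARR16), a type-A response regulator, which rose by 1.56 (SE 0.30, adjusted p = 0.0147). The RR16 call ended without ethylene 1-2 (0.0564), and over all arrays with the block its adjusted p was 0.000555.

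**Figure D2:**
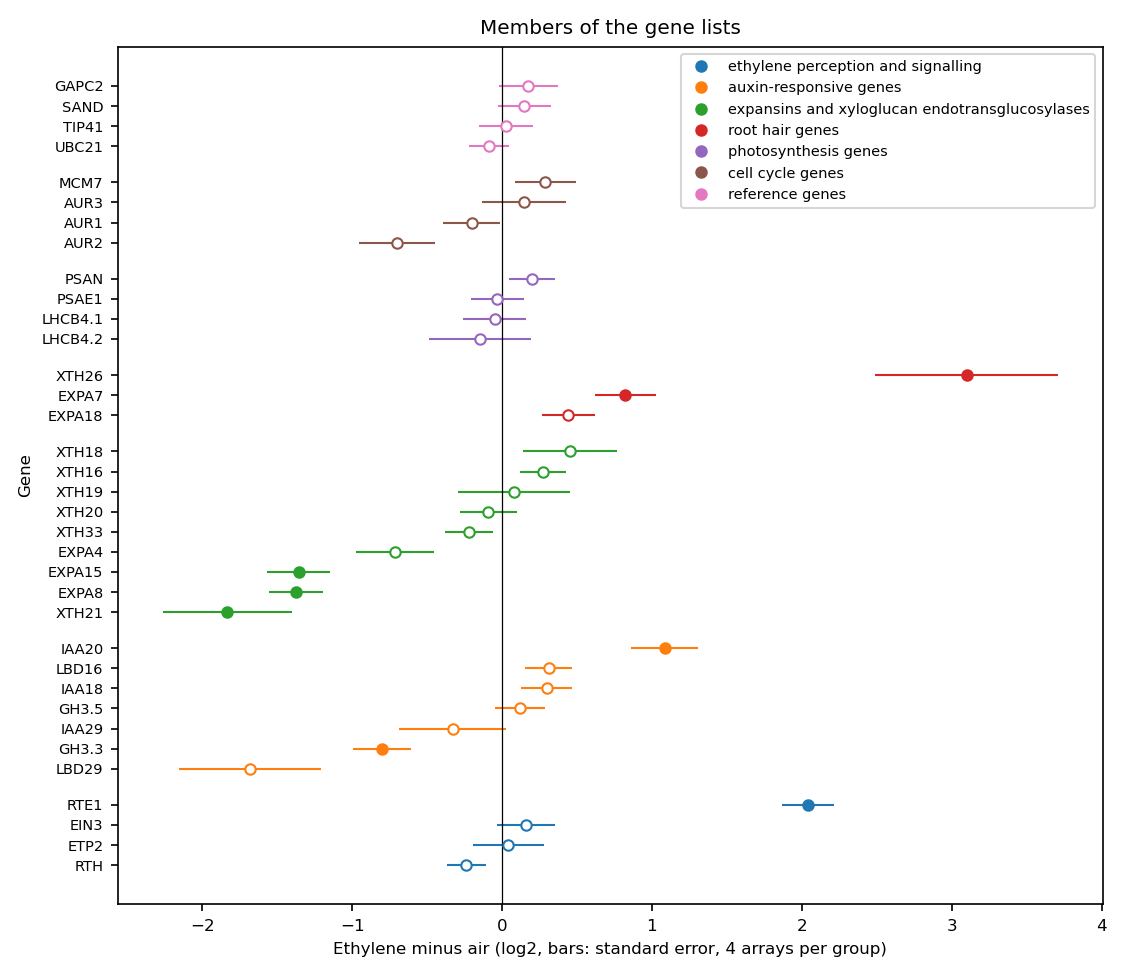
Log2 difference between ethylene and air (horizontal axis) of the tested members of 7 gene lists, with standard errors from limma and 4 arrays per group. Filled points passed an adjusted p of 0.05 and open points did not; XTH26, which has a wide standard error, and RTE1 at 2.04 lie farthest to the right and XTH21 at −1.83 farthest to the left among those that passed.

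No tested member passed in the lists of cell cycle genes (4 tested), photosynthesis genes (4), gibberellin metabolism and signalling (3) and reference genes (4), with or without the experiment as a block, when adjusted over all probe sets. With the block and adjustment over the list alone AUR2 fell (adjusted p = 0.0437), and so did GID1A (0.0207), while GID1B and GID1C rose (0.0256 and 0.0207), the last 2 named after their values were seen. The camera adjusted p was 0.84 for each of these 4 lists, and neither form of fry passed. Their members with the smallest p were AUR2, an Aurora kinase gene, at −0.70 (SE 0.25, adjusted p = 0.205), PSAN, of photosystem I, at 0.20 (SE 0.15, adjusted p = 0.675), the gibberellin receptor gene GID1A at −0.41 (SE 0.16, adjusted p = 0.279) and GAPC2 at 0.18 (SE 0.19, adjusted p = 0.802). AUR2 passed with the 4 pairs as a block (0.0417) and with averaged replicas and a block (0.0342), but not with the experiment as a block (0.078). For photosynthesis genes camera pointed upward while the mean and median were slightly negative, and the mean turned positive with median scaling. Of the chlorophyll synthesis genes, PORB, which makes chlorophyllide in light, differed by 0.60 (SE 0.21, adjusted p = 0.172), from 30797 ± 3478 to 47949 ± 14258. PORB passed with the experiment as a block (0.0247) and when adjusted over the list alone, and CHLM did not.

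Lists of other stresses, organs and stages gave few measured genes, and none passed with or without the experiment as a block when adjusted over all probe sets. LDH1 (AT4G17260) of the hypoxia list differed by 0.27, STZ (also ZAT10) of the touch, cold and wounding list by 0.58, and WAG2, of the list of apical hook and etiolated growth regulators, by 0.29. STZ passed with the 4 pairs as a block (0.048) and with averaged replicas and a block (0.0254). The lists of STZ and WAG2 each had 1 tested member, so adjustment over the list alone leaves the limma p as it was. Blocking by experiment, this p was 0.0119 for STZ and 0.0373 for WAG2. Adjusted over all probe sets it was 0.0833 and 0.179, so neither passed with that block. For the heat shock list, the smallest p was that of the HSP22 gene, at −0.11. ICL, an isocitrate lyase gene used in mobilising seed oil, was at 70328 ± 17439 in air and 84318 ± 20894 in ethylene, a difference of 0.26. PDF1.2b, of the jasmonate and defence list, differed by 0.02 (SE 0.48), on a probe set that may also bind related genes by its type. Its differences in experiments 1 and 2 were opposite, −0.85 and 0.90, so its mean does not show that it was unchanged. The lists of AP2/ERF transcription factors, brassinosteroid genes, root cell types, shoot apex and epidermis, and vascular tissue had no member with a named probe set and were not tested. The measured lists therefore leave open how the makeup of cell types compared between the groups.

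The response to ethylene was also measured in each of the 2 experiments on its own. Within experiment 1, 404 probe sets were higher and 581 lower in ethylene, and within experiment 2, 379 were higher and 617 lower. Of the probe sets called in both, 556 had the same direction and 1 the opposite, in tests that share 1 estimate of the spread. Fits to the arrays of a single experiment gave 374 higher and 499 lower in experiment 1, and 387 and 641 in experiment 2. AT5G40590 rose by 4.78 in experiment 1 and 5.22 in experiment 2, GH9B12 by 2.45 and 3.09, and AT5G19890 by 4.16 and 4.35. CYP718 rose by 4.72 and 2.99, and AT1G29660 fell by 4.94 and 3.00. The differences in EXPA8 were −1.57 and −1.18, and in SWEET17 −2.12 and −2.71. Over the tested probe sets, which are not independent replicates, the log2 differences of the 2 experiments correlated with r = 0.591 (rho = 0.431). For the 655 probe sets called over all arrays r was 0.949, the direction was shared by all 655, and the median size was 1.14 in experiment 1 and 1.09 in experiment 2, a comparison made on probe sets chosen from the same arrays. The ethylene effect differed between experiments for 0 probe sets in limma (smallest adjusted p = 0.107), and 917 had an unadjusted p under 0.05 where 796 would by chance.

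**Figure D3:**
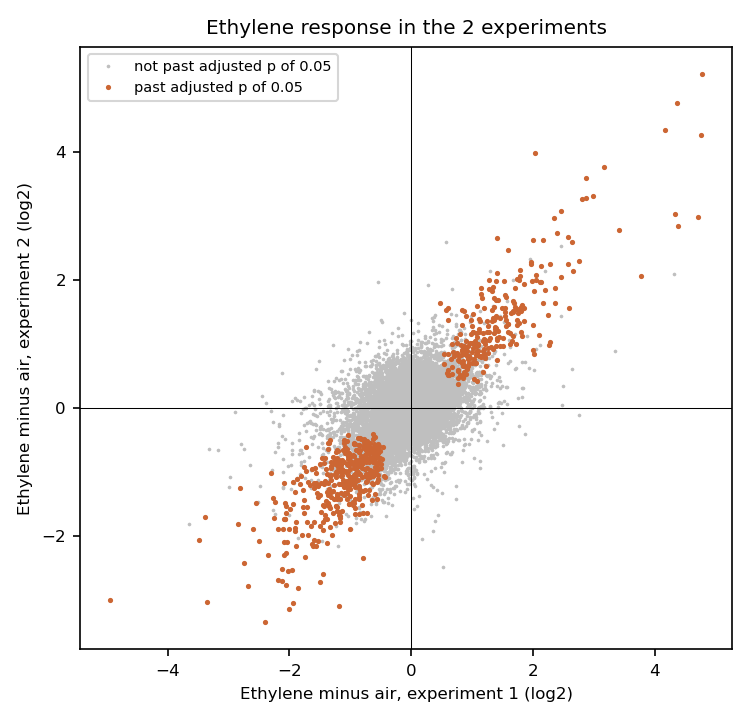
Log2 difference between ethylene and air in experiment 1 (horizontal axis) and experiment 2 (vertical axis) for each of the 15922 tested probe sets. Orange points are the 655 probe sets past an adjusted p of 0.05 over all 8 arrays and grey points the others; the orange points have the same sign in both experiments, with r = 0.949.

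The experiments themselves also differed. Averaged over air and ethylene, 2898 probe sets were higher and 1980 lower in experiment 2 than in experiment 1. The first principal component held 39.6% of the variance and separated the experiments, and the second held 27.4% and separated air from ethylene. Arrays of one group and experiment correlated over tested probe sets with r of 0.964 to 0.979, arrays of different groups in one experiment with 0.938 to 0.955, and arrays of one group in different experiments with 0.923 to 0.946. The geometric mean intensity of the spike-in controls was 14906 and 19255 on the air arrays of experiment 1 and 4116 and 4780 on those of experiment 2. On the ethylene arrays it was 13042 and 15624 in experiment 1 and 3611 and 10754 in experiment 2, so that ethylene 2-2 stood apart from the other arrays of its experiment. The ratio of 3' to 5' probe sets of control transcripts, a sign of RNA integrity, lay between 1.14 and 1.69 for actin and between 1.13 and 1.48 for ubiquitin. For GAPDH it was 0.68 to 0.78 in experiment 1 and 0.99 to 1.08 in experiment 2, except for 0.78 on ethylene 2-2. The actin ratio was lower in ethylene in all 4 same-numbered pairs, by 0.13 on the log2 scale (SE 0.13, or 0.097 with the experiment as a block), with an exact permutation p within experiments of 0.333, a test added after the ratios were seen. Of the 64 control probe sets, 0 passed in limma and 0 had an unadjusted p under 0.05, with or without the experiment as a block, where 3.2 would by chance. The SE of the log2 spike-in level between ethylene and air was 0.40 with the block, so shifts of that size are not excluded.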

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

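A sample far from the others of its group was looked for among the named genes and the array-level measures. AT4G36610 had a log2 intensity of 12.413 on air 2-1, while the other 3 air arrays lay between 12.067 and 12.101, so that the gap was 0.902 of the range. AT5G40590 had a log2 intensity of 12.414 on ethylene 1-1, while the other 3 ethylene arrays lay between 13.047 and 13.164, a gap of 0.844 of the range. Both gaps are above the critical value of Dixon's test for 4 samples at the 5% level. Chance alone marks about 5% of groups of 4 like samples, or 4.4 of the 88 examined here, and 2 were found. Each group held arrays of 2 experiments that differed, so this expectation is approximate. In both genes the ethylene and air arrays remained apart.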

How the results depend on the processing

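A blocked model without ethylene 2-2 and a larger pseudocount were chosen after seeing the data, and the rest beforehand. Of the values for counts and gene lists under the alternatives, 253 stayed on their side of the threshold or within 1.5 times. Another 24 counts moved further, 6 list values lost the call and 2 gained it. Most of the 253 belong to lists that did not pass in the main fit and had no call to lose. A reversal was counted only for a list or gene that passed in the main fit or the alternative, and there was none. Lists that passed in neither could change direction. The auxin-responsive list, upward in the main fit, pointed down with the 4 pairs, with averaged replicas and in experiment 1 alone. The photosynthesis, gibberellin and reference lists also turned under some alternatives. The count of higher probe sets, 249, became 689 and that of lower ones, 406, became 1170 with the experiment as a replicate block, 643 and 1133 with the 4 pairs as a block, 747 and 1255 with averaged replicas and a block, 119 and 130 with replicas as a random block, and 574 and 997 in the blocked model without ethylene 2-2. Experiment 1 alone gave 374 higher, and experiment 2 alone 387 higher and 641 lower. Leaving out 1 array gave 164 to 204 higher and 214 to 315 lower. Of probe sets at least 2-fold changed, 345 were lower with the 4 pairs, 369 with averaged replicas and 364 in experiment 2 alone, and 114 were higher and 118 lower with the random block. A block takes the difference between experiments out of the spread. Leaving out arrays gives fewer samples, and leaving out 1 without a block also gives unequal numbers from the experiments. The random block estimated a correlation of 0.458 between replicas within a group and experiment, which the main model treats as independent. Such a correlation raises the error of the comparison. The cause of the other shifts was not tested. The adjusted p of the ethylene perception list, 0.256, was 0.0173 with fry and 0.0442 in experiment 1 alone. That of expansins and xyloglucan endotransglucosylases, 0.0196, was 0.174 with an estimated correlation, 0.156 with 50% of probe sets left out, 0.265 in experiment 2 alone, and 0.00816 to 0.0533 with 1 array left out. That of root hair genes, 0.0018, was 0.174 with an estimated correlation, and the cause was not tested. Among named genes 801 values stayed on their side, 50 lost the call, 12 gained it and none reversed in the sense given above. The 801 include values of genes not called in the main fit. The 50 losses fell on XTH26, AT1G29660, AT5G41900, IAA20, GH3.3, XTH21, EXPA7 and RR16. All 24 called genes were kept with each replicate block, including the blocked model without ethylene 2-2. The experiment as a block added ACO3 and PORB and changed no other call of a gene chosen by the rule. It changed no set test of a planned list, though it added the list members EXPA4, EXPA18 and LBD29. AUR2 and STZ passed with the 4 pairs and with averaged replicas, but not with the experiment as a block. Averaging leaves 4 values per probe set for 3 terms. Its p-values rest mostly on the spread borrowed from other probe sets and are weak support for a call. Same-numbered replicas were not consistently more alike than other pairs of an experiment, so the 4 pairs may be arbitrary. With the random block IAA20, GH3.3, XTH21, EXPA7 and RR16 were lost. The difference between experiments stayed at 0 probe sets under the 4 alternatives run, with smallest adjusted p of 0.0784 to 0.236. Set tests were not run with the random block, and the root hair list had under 3 members with 50% left out or a pseudocount of 1. Without detection calls, how far dim signals stand above background is unknown.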

Other observations

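Further gene families were formed from symbols after the annotation had been seen, and the genes named in this paragraph were chosen after their values were seen. Of 36 families, 29 were tested as sets, and 1, the expansin family, passed with camera. Of its 14 tested members, 5 of which also stand on the lists of the report, 1 rose and 4 fell, or 2 and 7 with the experiment as a block. EXPB1 fell by 2.02 on the log2 scale (SE 0.26, limma adjusted p = 0.00149) and EXLA2 by 0.89 (SE 0.14, adjusted p = 0.00541), beside EXPA8 and EXPA15. The camera adjusted p of the family was 0.00334, and 0.752 with an estimated correlation. Fry gave it an adjusted p of 0.0264, and the mixed form of fry 9.32e-05, a form that other families passed too. The mean of the family was −0.55 with the deposited scaling and −0.54 with quantile or median scaling, and EXPA7, its member that rose, did not pass with median scaling. Members of 15 families passed singly, or of 23 with the experiment as a block. TBL37, of a family of wall polysaccharide acetyltransferases, fell by 2.16, from 9298 ± 1186 to 2058 ± 76.9 (mean ± SD, n = 4). PME61, a pectin methylesterase gene, fell by 1.70, and the defensin-like gene PDF2.5 rose by 1.54. Of 12 tested IQD genes, which encode calmodulin-binding proteins, iqd15 rose by 2.00, and 4 rose with the experiment as a block. Of 14 tested serine carboxypeptidase-like genes 3 fell, but 1 with quantile or median scaling, while 1 rose and 5 fell with the experiment as a block. Of 35 tested UDP-glycosyltransferase genes 1 fell, or 2 with median scaling and 2 of 34 with quantile scaling. In the model with the experiment as a block 1 rose and 7 fell. There the family passed as a set with camera (adjusted p = 0.0381, but adjusted p = 0.62 with an estimated correlation). None of 9 nuclear light-harvesting and photosystem genes passed. Of 68 genes encoded in the plastid none passed, but psbB (−1.44, adjusted p = 0.00647) and rps14 (−1.68, adjusted p = 0.0217) were lower with the experiment as a block.

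Of the tests that follow, those on scaling, on spike-in brightness and on a wrong label, and the tests of gene families and the splits within experiments, were chosen only after the result was seen. The first question was whether chance groupings of the arrays give as many calls. Of the 35 splits of the 8 arrays into 4 and 4, 2 gave at least the 655 probe sets of the comparison of ethylene with air, so that the count over all splits does not exclude chance. The other one is the split of experiment 1 from experiment 2, which gave 3009 and points to a structure of the samples, and the highest of the remaining splits gave 0. For probe sets at least 2-fold changed the count was also 2, with 401 for ethylene against air, 698 for the experiments and 0 for the rest. Among the 8 splits that part all 4 pairs, too few for a share under 0.05, the highest other gave 0. Among the 18 splits with 2 arrays of each experiment on each side, also too few for a share under 0.05, the model with the experiment as a block called at most 1 probe set for another split. With the experiment as a block 1859 probe sets were called for ethylene against air, and within the experiments 985 and 996.

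More probe sets were lower than higher, 62.0% of the calls. If the scaling of the arrays were the cause, quantile normalisation was to bring the share to 50% or less, and it gave 61.4%. If noise of dim probe sets were the cause, the share was to vanish among the brightest of 3 equal groups of probe sets, where it was 60.6%. The first value argues against differences between arrays that quantile normalisation removes. It cannot test a shift of most genes, since both scalings assume there is none. The share was 62.4% in the middle group and 64.2% in the dimmest, so the excess of falls was not confined to dim probe sets. The share was 52.1% without air 2-1 and 52.2% with replicas as a random block, the cause of these drops was not tested, and whether the share may reflect a response to ethylene stays open.

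The experiments differed at more probe sets than the treatments did, and the spike-in controls were several times brighter in experiment 1. If array brightness were the cause, ethylene 2-2, whose spike-in level lay at 0.206 of the way from the ethylene arrays of experiment 1 to ethylene 2-1, should lie near experiment 1 in its other probe sets too. Over 2756 probe sets chosen on the air arrays alone it lay at 0.819 of the way, which argues against brightness as the whole cause. A wrong experiment label for this array is also argued against, since it correlated with ethylene 2-1 at r = 0.972 and with the ethylene arrays of experiment 1 at 0.932 and 0.946. Differences in growth, harvest or labelling between the experiments could account for the pattern and were not tested.

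Since 2 GDSL esterase/lipase genes had the largest falls among named genes and 2 class III peroxidase genes were among the largest rises, a hypothesis was that the other members of each family moved alike. Another 2 GDSL genes, AT3G50400 and AT1G74460, with differences of −2.29 and −1.91, had also been seen and were left out of the test. Over all 38 tested GDSL genes the mean was −0.57, and 1 rose and 6 fell, or 3 and 13 with the experiment as a block, and over all 40 tested peroxidase genes it was 0.28, and 3 rose and 3 fell, or 12 and 7 with the block. Both means hold the genes that prompted the question. Over the 34 tested GDSL genes whose values had not been seen, the mean difference was −0.30 (SE 0.16, or 0.080 with the experiment as a block), with an exact two-sided permutation p of 0.143 over the 8 arrays. It was −0.46 in experiment 1 and −0.14 in experiment 2, and permuting only within experiments gave an exact p of 0.0556, the smallest that 36 arrangements can give. Of these 34, 1 rose and 2 fell, or 3 and 9 with the experiment as a block, and camera gave p = 0.00344, or p = 0.338 with an estimated correlation (0.00249 and 0.199 with the block), so that a shared fall may exist but was not settled. Over 38 unseen peroxidase genes the mean difference was 0.102 (SE 0.089, or 0.097 with the block), with an exact two-sided permutation p of 0.314, or 0.333 within experiments, and a camera p of 0.695, or 0.494 with the block. Of these 38, 1 rose and 3 fell, or 10 and 7 with the experiment as a block, which leaves a shared rise of the family open and shows members moving in both directions.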
